A study of Mus musculus with 12 samples.

How the data were processed

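Total RNA from the hippocampus of 12 mice was hybridised to an nCounter gene panel, per the labels' protocols, and the mice fell into 4 groups of 3 by genotype and sex, taken from the sample labels. The labels number the samples within a group and call them separate samples, and p-values measure the spread between them. The deposited table holds normalized signal values, which the authors made with the nCounter Advanced Analysis tools, per the series' design text. Each gene value above 20 is a whole count times 1 factor for its sample, within 0.01 for 100% of such values, with factors from 0.82 to 1.27. Values below 20 were set to 20, and control rows are unscaled counts. How the factors were chosen is not given in the sources used here, and sample medians differed by 0.26 on the log2 scale. The floor hides the true level of low genes. The labels' protocol points to a metabolic panel, whereas the 770 genes of the table are largely neuroinflammation genes, so that several fixed lists had few members. The counts behind the values above the floor ranged from 281838 to 418467 per mouse. Of the gene symbols, 763 matched a current symbol in the reference gene table and 7 a synonym, and no coordinates are given because no genome build is stated.

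Values were taken as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups, moderated variances with a trend and Benjamini-Hochberg adjustment at 0.05 in each of 5 contrasts: genotype over both sexes, in females and in males, the genotype by sex interaction, and sex over both genotypes. The filter fixed before the data were examined, 20 or more in at least 3 samples, removed nothing because of the floor, so it was applied as above 20 in at least 3 samples, which kept 608 genes. Count models were not used, since the floor and the unscaled control rows left no complete count table. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, for the 19 of 37 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists of a contrast. The genes named are, for each contrast other than the interaction, those past the threshold, filled to 20 by p, for the interaction the 5 with the smallest p, up to 4 members of a list, and a fixed set around OGG1, DNA sensing and inflammation. The sex-linked genes Uty, Kdm5d, Kdm5c and Kdm6a are named for the sex contrast alone. Several of the fixed set (Tbk1, Isg15, Tlr9, Tfam, Polg and Gfap) were not analysed here.

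The scripts were tested on simulated counts drawn from the real means and spreads, with 200 changed genes. For the genotype effect over both sexes, simulated on 606 genes, 86.7% of genes changed 1.5-fold were recovered. For the interaction, simulated on 608 genes, 43.8% of genes changed 1.5-fold and 85.5% of those changed 2-fold were recovered. Genes were drawn independently of each other, in a single draw per contrast. With 200 changed genes the adjusted threshold is easier to pass than with the 8 calls of the real data over both sexes. These shares therefore do not bound what the real tests could miss. The lowest chi-square per degree of freedom between replicates of a group was 2.47 over 12 pairs, so that no library appeared deposited more than once within a group. Pairs across groups were not compared. Alternatives to the pseudocount, filter, scaling, variance model, adjustment, sample weights, samples and list test were run, with 6 kinds of alternative added after seeing the data: scaling on 12 panel reference genes, scaling on the positive controls, Slc17a6 or Ttr as a covariate, a filter for genes above the floor in all samples, sample weights estimated gene by gene because the default estimation did not converge, and the samples with Slc17a6 below 1000 alone. Correlations between samples used deviations from group means and exact two-sided permutation within groups over 1296 orders. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.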

Results

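Gene expression in the hippocampus was measured with the NanoString nCounter assay, in which barcoded probes are counted one molecule at a time without amplification, in 12 C57BL6/J mice aged 13 months. Mice labelled mtOGG1, which by the series title express the DNA repair enzyme OGG1 (8-oxoguanine DNA glycosylase) in mitochondria, were set against control mice, with 3 females and 3 males of each genotype. The table held 770 genes, 6 positive controls and 8 negative controls. The whole counts behind the normalized values of genes above the floor summed to between 281838 and 418467 per mouse. Values below 20 had been raised to 20, and the highest negative control reached 14 counts. Of the 770 genes, 131 stood at this floor in every mouse, and 608 that exceeded it in at least 3 mice were tested. Levels are given as normalized counts, and fold changes come from log2(value + 1), which understates the change of genes near the floor.

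The first comparison asked which transcripts differed between mtOGG1 and control mice over both sexes. The immediate early genes Arc, Fos and Egr1, which neurons transcribe within minutes of activity, were lower in mtOGG1 mice. Arc stood at 1144 ± 458 (SD, n = 6) in controls and 350.3 ± 125 (SD, n = 6) in mtOGG1 mice, a log2 fold change of -1.70 with a standard error of 0.20 (limma, adjusted p = 3.87e-04). Fos fell from 542 ± 224 (SD, n = 6) to 179 ± 73.6 (SD, n = 6), a log2 fold change of -1.62 with a standard error of 0.21 (limma, adjusted p = 5.52e-04). Egr1 fell from 3147 ± 577 (SD, n = 6) to 1810 ± 735 (SD, n = 6), a log2 fold change of -0.88 with a standard error of 0.20 (limma, adjusted p = 0.0486). The Egr1 call lay at the threshold. With its value nearly unchanged it was lost at pseudocounts of 5 and 20, with a mean of at least 50, after median centring, with panel reference genes, without a variance trend, with robust variances (adjusted p = 0.158) and with Benjamini-Yekutieli adjustment. Of 12 fits that each left out 1 mouse it was kept in 3, those without control female 3, mtOGG1 female 1 and mtOGG1 male 2. Each of the 6 mtOGG1 mice had less Arc and less Fos than every control mouse of its sex, and 5 of the 6 had less Egr1.

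**Figure D1:**
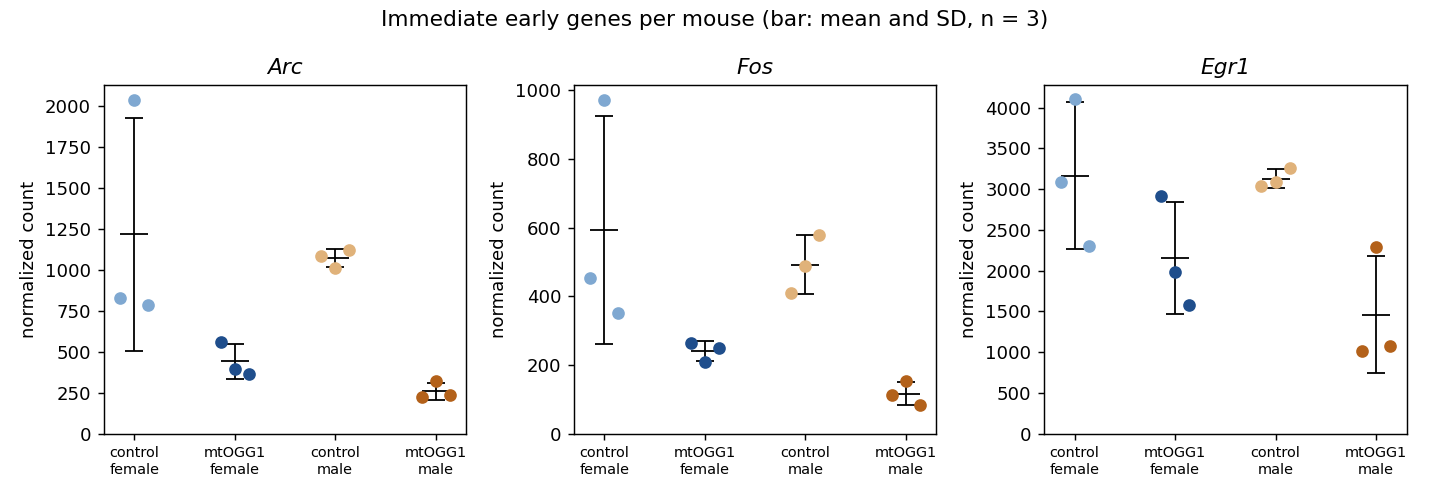
Normalized counts of Arc, Fos and Egr1 in each mouse (linear vertical axis from 0), with points for mice, and bars for the mean and SD of the 3 mice of a group. The mtOGG1 mice lie between 223 and 562 for Arc, and the controls between 785 and 2037.

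Altogether 8 of the 608 genes passed an adjusted p of 0.05 in the limma test, 1 higher and 7 lower in mtOGG1 mice. Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 172 ± 29.0 (SD, n = 6) to 95.2 ± 30.2 (SD, n = 6), with a log2 fold change of -0.90 (adjusted p = 0.0231). Ly6a, a membrane protein of brain endothelium, had a log2 fold change of -0.43 (adjusted p = 0.0486). Anxa1, encoding annexin A1, had a log2 fold change of -0.77 (adjusted p = 0.00655), and Lcn2, encoding lipocalin 2, a protein of reactive astrocytes, one of -0.80 (adjusted p = 0.0164). The Lcn2 value was -0.18 in females and -1.41 in males, and 3 of the 6 mtOGG1 mice had less than every control mouse of their sex. Tspan18, a tetraspanin, was higher with a log2 fold change of 0.74 (adjusted p = 0.0486). The last 3 genes lay near the floor: Lcn2 was at 20 in 4 of the 6 mtOGG1 mice and Tspan18 in 5 of the 6 control mice, so that their folds are understated. With 1 mouse left out, Arc, Fos and Anxa1 passed in 12 of 12 fits. Lcn2 passed in 9 (not without mtOGG1 female 3, control male 1 or control male 2), Cdkn1a in 8 (not without control female 1, mtOGG1 female 3, control male 2 or control male 3). Ly6a passed in 3 (those without control female 2, control female 3 or mtOGG1 male 1) and Tspan18 in 3 (those without mtOGG1 female 1, mtOGG1 male 1 or mtOGG1 male 2). The mtOGG1 mice also had more Slc17a6, a vesicular glutamate transporter most abundant in neurons below the cortex, at 956 ± 505 (SD, n = 6) against 505 ± 395 (SD, n = 6), a log2 fold change of 1.06 that did not pass the test (adjusted p = 0.401). With Slc17a6 as a covariate, chosen after seeing the data, Arc, Fos, Anxa1 and Lcn2 kept an adjusted p under 0.05. This was not so for Egr1 (log2 fold change -0.55, adjusted p = 0.107), Cdkn1a (log2 fold change -0.71, adjusted p = 0.0549), Ly6a (log2 fold change -0.41, adjusted p = 0.107) and Tspan18 (log2 fold change 0.58, adjusted p = 0.151). The 8 calls became 0 without the filter on low values and 0 without moderation of the variances, 37 with sample weights, whose estimation did not converge, and 29 with weights estimated gene by gene. Removing the filter added 162 genes, 131 of them at the floor in every mouse. Arc, Fos and Anxa1 kept their values there, each at an adjusted p of 0.0517 (limma).

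The next 12 genes by p did not pass the test. Their log2 fold changes were -0.39 for Srgn, -0.71 for Hspb1, -0.50 for Ptgs2 (each adjusted p = 0.0722), -0.34 for Tbp (adjusted p = 0.0797), 0.36 for Opalin (adjusted p = 0.0917) and -0.41 for Ifih1, a sensor of viral RNA (adjusted p = 0.0968). Igsf10 and Plxdc2 had positive values of 0.37 and 0.25, and Gdpd2 one of 0.51. S100a10, H2-T23 and Cx3cl1 had negative values of -0.29, -0.51 and -0.40. The mouse Ogg1 transcript was read at 41.8 ± 3.54 (SD, n = 6) in controls and 41.9 ± 7.90 (SD, n = 6) in mtOGG1 mice, a log2 fold change of -0.01 with a 95% interval from -0.27 to 0.25 (limma, adjusted p = 0.967). The labels do not say whether this probe reads the transgene, so that its level does not check the genotype.

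Among the 19 gene lists with at least 5 tested members, 2 passed the test over both sexes. The immediate early genes were lower, with 4 of 6 tested members below 0 and a median log2 fold change of -0.77 (camera, adjusted p = 8.23e-05, and adjusted p = 0.542 with an estimated correlation). Of these members 3 passed over all genes tested, and 4 passed when adjusted over the list alone, Homer1 being the added one at -0.67. Jun and Myc had values of 0.03 and 0.02. The oligodendrocyte markers were higher, with all 10 tested members above 0 and a median of 0.23 (camera, adjusted p = 1.52e-04, and adjusted p = 0.845 with an estimated correlation). None of them passed over all genes tested or adjusted over the list alone, and the values of the myelin genes Cnp and Mog were 0.29 and 0.27. Slc17a6 was higher beside both lists, with the levels given above. With it as a covariate the oligodendrocyte median was 0.04 and no longer passed (adjusted p = 0.268), while the immediate early genes still did at a median of -0.39. The oligodendrocyte call was also lost with Tbp scaling, which moved the median of all genes to 0.335 (list median 0.58, adjusted p = 0.192). In the samples with low Slc17a6, which leave 1 mtOGG1 male, the medians were 0.13 for the oligodendrocyte markers and -0.38 for the immediate early genes. On ranks the immediate early genes missed the threshold (adjusted p = 0.0678).

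The lists nearest to the subject of the series, inflammation and the sensing of DNA in the cytosol, did not pass the test. The 14 tested genes of cytosolic DNA sensing and the interferon response had a median log2 fold change of -0.04 (camera, adjusted p = 0.411), with 8 members below 0 and 6 above. Among them Irf7 had a value of -0.36, Ifitm3 -0.40 and Irf3 -0.04, and none passed over all genes tested, whereas 1, Ifih1, passed when adjusted over the list alone. The DNA sensor gene Mb21d1, which encodes cGAS, and the cytokine genes Il1b and Tnf stood at the floor in all 12 mice. Tmem173, which encodes STING, exceeded it in 2 mice and Nlrp3 in 1, so that differences in these genes were not detectable at this depth. The 30 Toll-like receptor and NF-kB genes had a median of -0.07 (adjusted p = 0.369), with Ptgs2 passing when adjusted over the list alone. The 18 cytokines, chemokines and their receptors had a median of 0.06 (adjusted p = 0.411). The 7 antigen presentation genes had a median of 0.02 and a mean of -0.11 that differed in sign, with a test direction of lower (adjusted p = 0.502), and H2-T23 passed when adjusted over the list alone.

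Markers of the other cell types did not pass over both sexes. The 31 microglia and macrophage genes had a median log2 fold change of -0.00426, with 14 above 0 and 17 below, although the camera direction was higher (adjusted p = 0.763), and Cx3cr1 had a value of 0.16. The 7 genes of disease-associated microglia had a median of 0.07 (adjusted p = 0.251), the 9 astrocyte genes 0.04 with a mean of -0.00900 (adjusted p = 0.590) and the 12 neuron genes -0.06 (adjusted p = 0.763). The 7 endothelial and pericyte genes were all below 0, with a median of -0.17 (adjusted p = 0.0978), Esam at -0.32 and Tie1 at -0.34. The 25 DNA repair genes had a median of 0.03 (adjusted p = 0.502) and the 13 oxidative stress genes 0.02 (adjusted p = 0.763). The medians were 0.06 for 12 lysosome genes (adjusted p = 0.115), -0.04 for 15 autophagy genes (adjusted p = 0.763), -0.02 for 5 genes of mTOR and AMPK signalling (adjusted p = 0.825), -0.09 for 21 of PI3K and MAPK signalling (adjusted p = 0.227), -0.13 for 6 hypoxia genes (adjusted p = 0.247) and 0.00496 for 21 genes of p53 and the cell cycle, whose mean was -0.06 (adjusted p = 0.724).

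The second comparison was made within females. No gene passed the limma test, which gave 18 genes at an unadjusted p under 0.05, and an ordinary linear model per gene also called 0. The genes with the smallest p were again Arc, at 1216 ± 711 (SD, n = 3) in control and 441 ± 105 (SD, n = 3) in mtOGG1 females, and Fos, at 592 ± 332 (SD, n = 3) and 241 ± 28.6 (SD, n = 3). Their log2 fold changes were -1.34 for Arc (limma, adjusted p = 0.194) and -1.16 for Fos (limma, adjusted p = 0.461), and Ptgs2, which encodes cyclooxygenase 2, had one of -0.64 (limma, adjusted p = 0.497). Without control female 2 the value for Fos was -0.73. The other 17 genes of smallest p had adjusted p of 1 and included Cdkn1a at -0.68, Ifitm2 at -0.44, Vim at -0.43, Casp1 at -0.46, Csf3r at 0.43 and Ercc2 at 0.29. Leaving out 1 mouse moved Cdkn1a to -0.41 (without mtOGG1 female 3), Vim to -0.26 (without control female 3) and Casp1 to -0.27 (without mtOGG1 female 2). The immediate early genes were the only list past the test in females, with 6 of 6 members below 0, a median log2 fold change of -0.52 (camera, adjusted p = 1.25e-06) and adjusted p = 0.260 with an estimated correlation. When adjusted over the list alone, 2 members passed. Slc17a6 had a log2 fold change of 0.75 in females (limma, adjusted p = 1), and with it as a covariate the list still passed, at a median of -0.29.

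The third comparison was made within males, where 6 genes passed, 1 higher and 5 lower in mtOGG1 mice. Arc fell from 1072 ± 55.8 (SD, n = 3) to 259 ± 53.2 (SD, n = 3), a log2 fold change of -2.06 with a standard error of 0.28 (limma, adjusted p = 0.00164). Fos fell from 492 ± 85.6 (SD, n = 3) to 117 ± 34.3 (SD, n = 3), a log2 fold change of -2.09 with a standard error of 0.30 (limma, adjusted p = 0.00164). Lcn2 fell from 57.5 ± 18.0 (SD, n = 3) to a value at or next to the floor in all 3 mtOGG1 males (limma, adjusted p = 0.00216), and Anxa1 fell from 52.6 ± 9.64 (SD, n = 3) to 23.02 ± 2.35 (SD, n = 3) (limma, adjusted p = 0.00297). Ly6a fell with a log2 fold change of -0.67 (limma, adjusted p = 0.0253). Opalin, a gene of myelinating oligodendrocytes, rose from 290 ± 30.5 (SD, n = 3) to 470 ± 44.4 (SD, n = 3), a log2 fold change of 0.70 (limma, adjusted p = 0.0155). With 1 mouse left out, Arc, Fos, Lcn2 and Anxa1 passed in 12 of 12 fits. Opalin passed in 9 (not without control male 1, mtOGG1 male 1 or mtOGG1 male 3) and Ly6a in 7 (not without control male 1, control male 2, control male 3, mtOGG1 male 2 or mtOGG1 male 3). Among the genes that missed the threshold, Cdkn1a had a value of -1.11, Egr1 -1.20, Hspb1 -1.01, Tspan18 1.01, Plxnb3 0.64 and Cidea 0.86. The 6 calls became 0 without the filter on low values and 0 without moderation of the variances, 12 after median centring with 3 higher and 9 lower, 115 with sample weights and 74 with weights estimated gene by gene. With Slc17a6 as a covariate Opalin (log2 fold change 0.62, adjusted p = 0.0525) and Ly6a (log2 fold change -0.64, adjusted p = 0.0572) did not pass.

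In males 3 gene lists passed the test. The oligodendrocyte markers were higher in mtOGG1 males, with 10 of 10 members above 0, a median log2 fold change of 0.36 (camera, adjusted p = 7.83e-06, and adjusted p = 0.538 with an estimated correlation) and values of 0.52 for Mog and 0.57 for Mag. Of these markers 5 passed when adjusted over the list alone and 0 over all genes tested. The immediate early genes were lower, with a median of -1.03 (camera, adjusted p = 0.00595, and adjusted p = 0.538 with an estimated correlation), 2 members passing over all genes tested and 4 adjusted over the list alone. The 7 endothelial and pericyte genes were lower, with a median of -0.33 (camera, adjusted p = 0.0338, and adjusted p = 0.538 with an estimated correlation), including Pecam1 at -0.40 and Flt1 at -0.36, although none passed singly. Scaling on Tbp moved the median of all genes in males to 0.489 and that of the endothelial genes to 0.19, below the other genes, where they still passed (adjusted p = 0.0192). Slc17a6 stood at 1077 ± 611 (SD, n = 3) in mtOGG1 males and 411 ± 274 (SD, n = 3) in control males, beside these lists. With Slc17a6 as a covariate the medians were 0.16 for the oligodendrocyte markers and -0.54 for the immediate early genes, which both still passed. The median was -0.28 for the endothelial and pericyte genes, which did not pass (adjusted p = 0.0828). The endothelial call was also lost at similar medians with Ttr as a covariate (-0.26, adjusted p = 0.0651), with both kinds of sample weights (-0.30, adjusted p = 0.134, and -0.33, adjusted p = 0.111) and with a mean of at least 50 (-0.36, adjusted p = 0.0549). It was lost too without mtOGG1 female 1, mtOGG1 female 3, control male 2 (median -0.22) or mtOGG1 male 2. The immediate early call was lost on ranks (adjusted p = 0.251), and passed at a median of -0.52 with Tbp scaling. The oligodendrocyte call was lost with Tbp scaling at a larger median of 0.88 (adjusted p = 0.0884). In the samples with low Slc17a6, which leave 1 mtOGG1 male, the medians were -0.31 for the immediate early genes and 0.19 for the oligodendrocyte markers.

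**Figure D2:**
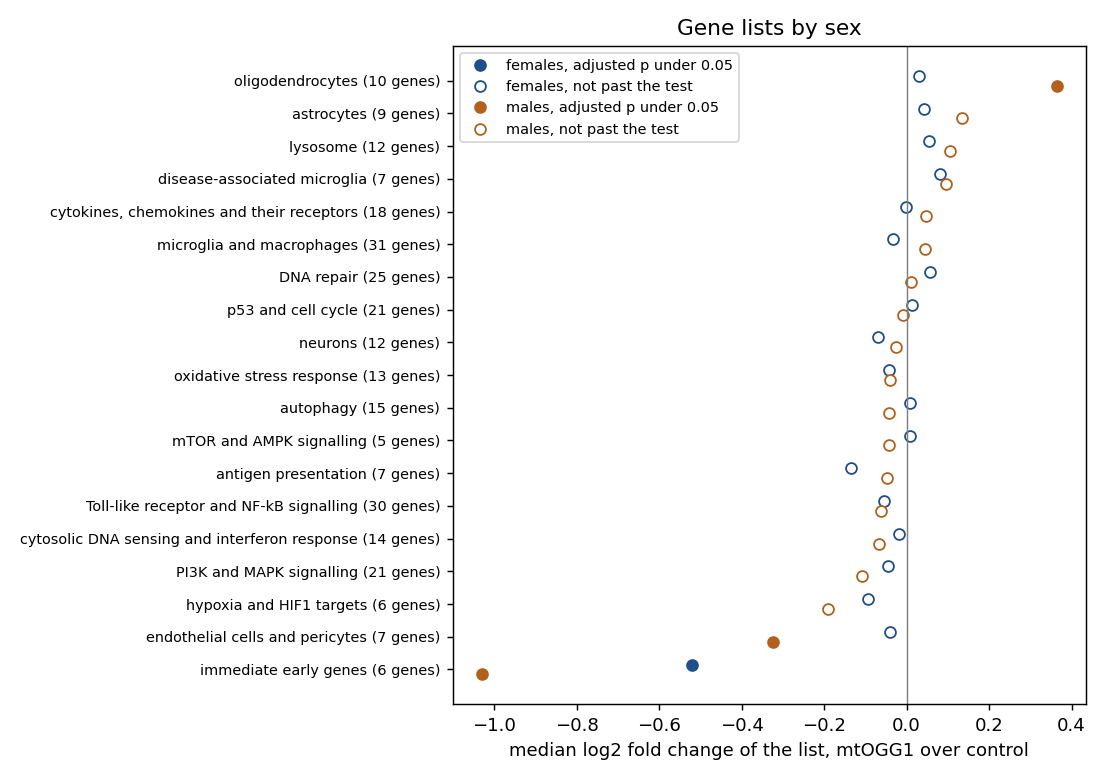
Median log2 fold change of each tested gene list, mtOGG1 over control (horizontal axis), in females and in males, with filled points for lists at an adjusted p under 0.05 (camera, preset correlation). The immediate early genes lie lowest in both sexes, at -0.52 in females and -1.03 in males, and the oligodendrocyte markers lie highest in males, at 0.36.

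The interaction asked whether the genotype difference itself differed between the sexes. No gene passed the limma test, 29 had an unadjusted p under 0.05 and an ordinary linear model called 0. The smallest p belonged to Lcn2, whose log2 fold change in females exceeded that in males by 1.23 (limma, adjusted p = 0.404), Itga7 with -0.96 (adjusted p = 0.404), Opalin with -0.68 (adjusted p = 0.604), Tradd with -0.88 and Enpp6 with -0.69 (each adjusted p = 0.892). For Arc this difference was 0.72 with a 95% interval from -0.14 to 1.58 (limma, adjusted p = 0.959), so that the calls made in males and missed in females are not shown to differ between the sexes. As a list, the oligodendrocyte markers had lower values in females than in males, with a median difference of -0.28 and 10 of 10 members below 0 (camera, adjusted p = 1.83e-04), and adjusted p = 0.962 with an estimated correlation. The median lay between -0.43 (without control male 2) and -0.16 (without mtOGG1 female 2) when 1 mouse was left out. It was -0.05 in the samples with low Slc17a6, which leave 1 mtOGG1 male. With Slc17a6 as a covariate it was -0.19, and the list still passed (camera, adjusted p = 6.29e-04). With Tbp scaling it was -0.61, without passing (adjusted p = 0.0537). It passed at -0.47 with sample weights, at -0.48 with weights estimated gene by gene and at -0.16 with Ttr as a covariate.

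**Figure D3:**
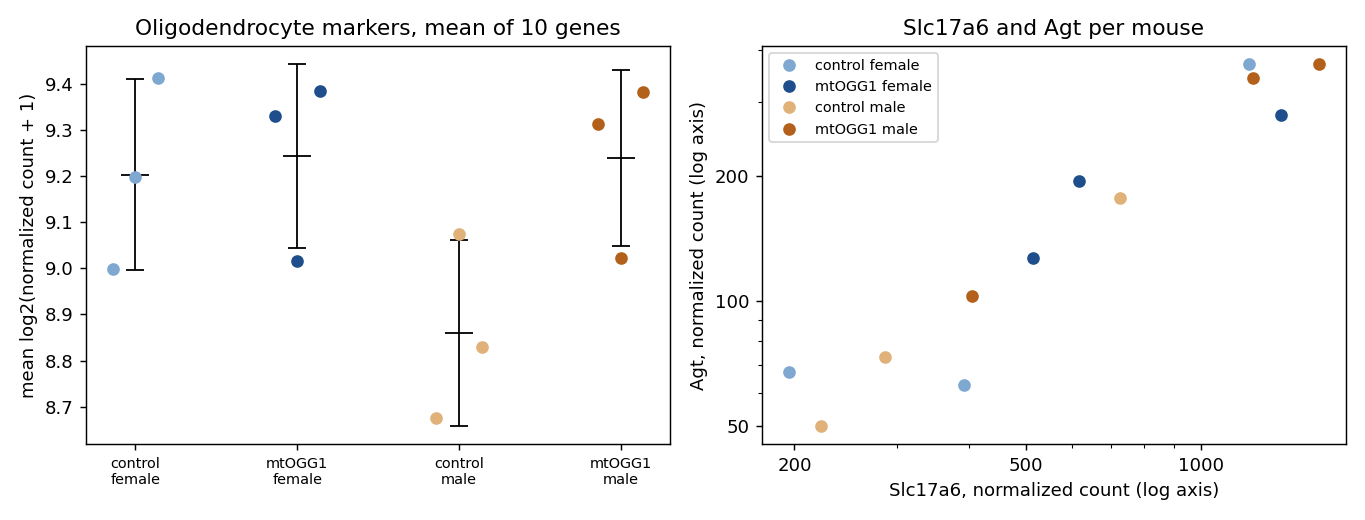
Left, the mean log2(normalized count + 1) of 10 oligodendrocyte markers in each mouse, with bars for the mean and SD of the 3 mice of a group. Right, normalized counts of Slc17a6 and Agt in each mouse on log axes, with Slc17a6 from 195 to 1597 and Agt from 49.8 to 371.

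The last comparison set the 6 females against the 6 males over both genotypes. The Y-linked genes Uty and Kdm5d stood at the floor in all 6 females and at 173 ± 8.18 (SD, n = 6) and 133 ± 16.7 (SD, n = 6) in males, as the sex labels require. The X-linked histone demethylase gene Kdm6a, which escapes X inactivation, was higher in females at 154 ± 16.1 (SD, n = 6) than in males at 101 ± 22.1 (SD, n = 6), a log2 fold change of 0.63 (limma, adjusted p = 0.0324). This call was kept in 3 of 12 fits that each left out 1 mouse (those without mtOGG1 female 3, control male 3 or mtOGG1 male 2). Opalin was higher in females at 525 ± 65.0 (SD, n = 6) than in males at 380 ± 104 (SD, n = 6), a log2 fold change of 0.50 (limma, adjusted p = 0.0207). This call was kept in 8 of those 12 fits (not without mtOGG1 female 1, mtOGG1 female 2, control male 1 or mtOGG1 male 2). The Opalin log2 fold change by genotype was 0.70 in males, and its interaction of -0.68 did not pass the test. By these values its difference by sex was larger in control than in mtOGG1 mice. Uty, Kdm5d, Kdm6a and Opalin were the 4 genes past the test, and Kdm5c at 0.35, Lcn2 at -0.63, Mcm5 at 0.47, Gadd45a at 0.48 and Lsr at -0.45 followed without passing it. The microglia and macrophage genes were higher in females, with 28 of 31 members above 0 and a median of 0.15 (camera, adjusted p = 0.0223), and so were the oligodendrocyte markers with 10 of 10 above 0 and a median of 0.21 (camera, adjusted p = 0.0454). Both had adjusted p = 0.996 with an estimated correlation, and the microglia median turned to -0.04 when samples were scaled on the positive controls, which moved the median of all genes from 0.04 to -0.15, and the list still passed (adjusted p = 0.0407). The oligodendrocyte median was 0.02 under that scaling, and 0.06 without passing the test with sample weights (adjusted p = 0.950). Per mouse, the mean log2 value of these markers ran from 8.675 to 9.075 in control males and from 8.998 to 9.412 in control females. In mtOGG1 mice it ran from 9.022 to 9.383 in males and from 9.016 to 9.385 in females. The difference by sex thus lay in the control mice, and the male, interaction and sex results for these markers share the low control males. The microglia call was lost with sample weights (median 0.14, camera, adjusted p = 0.0661) and with weights estimated gene by gene (median 0.15, camera, adjusted p = 0.0615). In the samples with low Slc17a6 the microglia median was 0.11. With 1 mouse left out, the microglia call was lost without control female 1, control female 3 or mtOGG1 female 1. The oligodendrocyte call was lost without control female 2, control female 3, mtOGG1 female 1, mtOGG1 female 3, control male 1, control male 3 or mtOGG1 male 2.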

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

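The tests of tissue and scaling for the immediate early genes, of scaling for the oligodendrocyte markers, and of the relation between Slc17a6 and Agt were chosen after the results they bear on had been seen.

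The oligodendrocyte markers stood out because the genotype difference differed between the sexes as a list, with a median of -0.279 for females minus males (camera, adjusted p = 1.83e-04, and adjusted p = 0.962 with an estimated correlation). With 1 mouse left out this median lay between -0.43 (without control male 2) and -0.16 (without mtOGG1 female 2). In the samples with low Slc17a6, which leave 1 mtOGG1 male, it was -0.05. With Slc17a6 as a covariate it was -0.19, and the list still passed (camera, adjusted p = 6.29e-04). In males the mean log2 fold change of the 10 markers was 0.38 with a 95% interval from 0.00333 to 0.756, and with Slc17a6 as a covariate it was 0.151 with an interval from -0.09 to 0.39, which is consistent with a larger share of tissue from outside the hippocampus in the mtOGG1 males, although camera still called the list in males with that covariate (median 0.16, adjusted p = 0.00837), within a range of adjusted p from 7.25e-07 to 0.538 over its alternatives. Median centring, which removes any factor common to all genes of a sample, left a mean of 0.3635 with an interval from 0.0654 to 0.662, and over 5 scalings the means ran from 0.3635 to 0.8907, which argues against scaling as the whole source, although an earlier rule, that the interval include 0 under any other scaling, had left scaling open, since under the positive-control scaling, at a mean of 0.4161, the wider interval reached -0.000865, and was replaced by centring after both values had been seen. In mtOGG1 females Slc17a6 was also higher (log2 fold change 0.75), without passing the test, while the mean of the 10 markers was 0.04. A response of oligodendrocytes to the genotype in males remains open and was not tested apart from tissue composition.

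Among low genes, 3 outside the tested set exceeded the floor in 2 mtOGG1 mice and in no control mouse. Of the 10 such genes above the floor in exactly 2 mice, 2 were so in control mice alone and 5 in 1 mouse of each genotype, and chance gives 2.27 in mtOGG1 mice alone. The mean of the 2 mtOGG1 mice was 22.56 for Ccl3, 29.87 for Hdc and 21.42 for Tmem173.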

How the results depend on the processing

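The scalings on panel reference genes and positive controls, the covariates, the filter for genes above the floor in all samples, the weights estimated gene by gene and the fit on samples with low Slc17a6 (8 of 12, leaving 1 mtOGG1 male, assumed to vary like the other groups) were chosen after seeing the data. Count models were not run. The estimation of the sample weights stopped short of its tolerance, so that their counts carry less ground than the others. Unless a reason is given, the cause was not tested. Over both sexes the 8 calls became 5 at a pseudocount of 5 or of 20, 0 with no filter and 0 without variance moderation. They became 15 after quantile normalization (6 higher and 9 lower), 3 with Benjamini-Yekutieli adjustment, 37 with sample weights and 29 with weights estimated gene by gene. The stricter filters removed Anxa1, Lcn2 and Tspan18 before testing. With genes above the floor in all samples the other 5 calls, Arc, Fos, Cdkn1a, Ly6a and Egr1, were all kept. A mean of at least 50 left 3 calls, with Ly6a and Egr1 tested and lost. Scaling on Tbp, the single fixed reference gene measured, with a log2 fold change of -0.34 in mtOGG1 mice that did not pass the test, moved the median of all genes to 0.335 and gave 408 calls over both sexes (402 higher) and 420 in males (414 higher). In females the 0 calls became 1 with sample weights and 1 with Ttr as a covariate. In males the 6 calls became 0 with no filter, 12 after median centring, 19 after quantile normalization (6 higher and 13 lower), 11 with panel reference genes and 11 with positive-control scaling (each 4 higher and 7 lower), 12 without a variance trend, 11 with robust variances, 0 without moderation, 115 with sample weights (59 higher and 56 lower), 74 with weights estimated gene by gene (38 higher and 36 lower), 10 with the groups compared alone and 0 in the samples with low Slc17a6. The interaction gave 2 calls with sample weights. The 4 calls by sex became 2, Uty and Kdm5d, with no filter, with panel reference genes, without moderation and with Benjamini-Yekutieli adjustment. Either kind of sample weights gave 7. With genes above the floor in all samples 2 genes were called, but Uty and Kdm5d, at the floor in all females, were not tested there. Positive-control scaling gave 5 calls by sex, 0 higher and 5 lower.

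Gene lists lost every call with an estimated correlation and with fry, 0 in each of the 5 contrasts. Over both sexes 2 lists became 1 with Tbp scaling, with Slc17a6 as a covariate and on ranks, and the 1 interaction list became 0 with Tbp scaling, at a larger median of -0.613. By sex 2 lists became 1 with no filter, a mean of at least 50, Tbp scaling, quantile normalization, panel reference genes and in the samples with low Slc17a6, and 0 with either kind of sample weights.

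Leaving out 1 mouse at a time gave 3 to 12 calls over both sexes: 3 without mtOGG1 female 3 or control male 2, 4 without control female 1, control male 1 or control male 3, 5 without mtOGG1 female 2 or mtOGG1 male 3 and 12 without mtOGG1 male 2. Arc, Fos and Anxa1 stayed past the threshold in 12 of 12 such fits. The range was 0 to 2 in females (2 without control female 3), 4 to 19 in males (4 without control male 1 or mtOGG1 male 3, 10 without mtOGG1 female 1, 11 without control female 2, 14 without mtOGG1 male 2 and 19 without mtOGG1 female 3), 0 to 1 for the interaction (1 without control male 3) and 2 to 5 by sex (2 without mtOGG1 female 1, mtOGG1 female 2 or control male 1). Lists ranged from 2 to 3 over both sexes and in males, 1 to 3 in females (3 without control female 2, 2 without control female 3 or mtOGG1 female 2) and for the interaction (3 without control female 2), and 0 to 2 by sex (0 without control female 3 or mtOGG1 female 1, and 1 without control female 1, control female 2, mtOGG1 female 3, control male 1, control male 3 or mtOGG1 male 2).

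Some values reversed. Ogg1 turned to 0.333 with Tbp scaling, 0.0335 with panel reference genes, 0.105 with sample weights, 0.08025 with weights estimated gene by gene, 0.0577 and 0.0195 with Slc17a6 and Ttr as covariates, 0.119 in the samples with low Slc17a6 and between -0.098 and 0.0515 when 1 mouse was left out. Irf3 turned to 0.304 with Tbp scaling, 0.00445 with panel reference genes and lay between -0.128 and 0.0303 with 1 mouse left out. Reversals under Tbp scaling follow its shift of all genes, to a median of 0.335 over both sexes and 0.489 in males, and say nothing of single genes or lists, which lie below that median. Tbp scaling turned S100a10 to 0.0516 over both sexes and 0.0559 in males, Kdm3a in males to 0.02 and the endothelial list in males to 0.186. Positive-control scaling turned Vamp7, Gria4 and the microglia list by sex to -0.013, -0.0219 and -0.0435, above the median of all genes, which it moved to -0.152. Of the other comparisons of a named gene or list with an alternative, 2525 gene values and 221 list values kept their direction and side of the threshold, 148 gene and 56 list values lost it and 176 gene values gained it. Whether the replicate numbers pair the mice is not known, since the labels do not say and the correlations were mixed. Of the same-numbered pairs, 2 of 6 across genotype and 3 of 6 across sex correlated above 0.1. Across genotype 1 of 6, and across sex 3 of 6, correlated best with their own number. With the replicate block the counts were 6 over both sexes, 0 in females, 9 in males, 0 for the interaction and 5 by sex. Genes at the floor of 20 limit what low transcripts can show.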

Other observations

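Of the tests below, those on Arc, Fos and Egr1 and on Slc17a6 and Agt were chosen after the result was seen.

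Transcripts of regions next to the hippocampus varied between mice of 1 group. Over all 12 mice Slc17a6 ranged from 195 to 1597, Agt, an astrocyte gene most abundant below the cortex, from 49.8 to 371, and Ttr, the transthyretin of the choroid plexus, from 20 to 1525. Of these 3 genes, Slc17a6 and Agt are also expressed by hippocampal cells. As deviations from group means in 12 mice, Slc17a6 and Agt correlated with Pearson r = 0.944 (exact permutation p = 0.00231, adjusted p = 0.0104 over 9 relations) and Spearman rho = 0.874 (exact permutation p = 0.0054), and r was 0.904 without the 2 mice farthest from the median. Slc17a6 and Ttr gave r = 0.817 (exact permutation p = 0.0054) and rho = 0.769 (exact permutation p = 0.027), with r = 0.668 without those 2 mice. Slc17a7, the glutamate transporter of hippocampal and cortical neurons, went the other way with r = -0.789 (exact permutation p = 0.00617) and rho = -0.762 (exact permutation p = 0.00694), with r = -0.771 without those 2. The smallest range of log2 Slc17a6 within a group was 1.41, against a range of 0.629 for the log2 scaling factors, which argues against scaling. Different amounts of neighbouring tissue may therefore have been dissected, as a hypothesis. No biological explanation was tested.

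The lower Arc, Fos and Egr1 in mtOGG1 mice were weighed against the same tissue difference, since as deviations from group means in 12 mice Egr1 (Pearson r = -0.717, exact permutation p = 0.037, adjusted p = 0.0476, Spearman rho = -0.671, adjusted p = 0.0576) and Homer1 (r = -0.879, exact permutation p = 0.000772, adjusted p = 0.00695, rho = -0.867) fell with rising Slc17a6, whereas for Arc (r = -0.401, exact permutation p = 0.475) and Fos (r = -0.345, exact permutation p = 0.495) no correlation was detected. The mean log2 fold change of Arc, Fos and Egr1, -1.40, was -1.177 with Slc17a6 as a covariate, with a 95% interval from -1.79 to -0.57. The tissue read through Slc17a6 is thus unlikely to be the whole source of this mean. These 3 genes are the list members that passed over both sexes, so their mean may be overstated. The median of the whole immediate early list, Homer1 included, went from -0.77 to -0.39, which leaves a share from tissue open for the list. For Egr1 alone the value went from -0.88 (limma, 95% interval from -1.31 to -0.45) to -0.552 (linear model, interval from -1.09 to -0.01), and its adjusted p rose to 0.107, so that a share from tissue stays open for Egr1. Over 5 other scalings the interval nearest to 0 belonged to Tbp scaling, with a mean of -1.058 and an interval from -1.56 to -0.55. The genotype stays open as a source, and so do handling and the time of day before death, which the labels do not give.

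Other splits of the samples, with genotype exchanged within a sex, or sex within a genotype for the sex effect, tested whether other groupings of the mice give as many calls. Over both sexes 2 of 100 splits, the real one included, gave at least the 8 calls seen, and the highest of the others gave 28. That split also had the widest gap in log2 Slc17a6 of those drawn, 1.66 against 1.06 for the real one, which points to a structure of the samples. For the sex effect 2 of 100 splits gave at least 4 calls, with 16 as the highest other, again in the split with the widest Slc17a6 gap. The Y-linked Uty and Kdm5d are among the 4 real calls. An exchange of sexes mixes their levels, so the rank of the real split was partly fixed in advance. For the interaction the real count of 0 fixes the outcome, since any split gives as many (100 of 100), so that nothing was tested, and the highest other gave 31. Within a sex there are only 10 splits, too few for a share under 0.05: in males the real split gave 6 calls (1 of 10 splits) and the highest other 0, and in females the real split and the highest other gave 0, which again fixes the outcome (10 of 10 splits).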
